A study of Mus musculus with 30 samples.

How the data were processed

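CD4+ T cells from the hearts and the spleens of C57BL/6J mice, 8 weeks old and 7 days after myocardial infarction, were profiled by droplet single-cell sequencing of the 5′ ends of transcripts together with T-cell receptor (TCR) chains. Heart and spleen were each represented by 3 libraries. How many mice went into a library is not given in the labels, so p-values measure the spread between these libraries. Per the labels, each library was loaded with about 12000 cells to recover about 6000, at which 5.4% of droplets were taken to hold several cells. HISAT2, Seurat and the mm10 genome build are named in the submitters' processing notes without versions or roles. The TCR assembler and the filters on cells and genes are not given in the sources used here.

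The deposited expression tables, 1 per tissue, hold natural log values: the authors' value for a gene in a cell equals the natural log of 1 plus the gene's count per 10000 counts of that cell, as tested on the files. Unique molecular identifier (UMI) counts were recovered by undoing the log and dividing every value of a cell by the smallest value of that cell, taken as 1 UMI. With a tolerance of 0.01, 100% of the values came out whole in 21079 heart cells and 23929 spleen cells. The recovered totals ranged from 36368829 to 69999593 UMIs per library, in 5984 to 9103 cells with medians of 4555 to 5905 UMIs per cell. The deposited TCR tables give, per the file headers, UMI counts and read counts for each assembled contig, in 1 table per library. The suffix of a cell barcode was read as the library number: 91.8% to 95.0% of the expression barcodes of a library were found in the TCR table of the same number, and 0.638% to 1.46% in the tables of other numbers. The expression tables held 15378 genes in heart and 15393 in spleen, and the 14416 genes in both could be compared between tissues.

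The authors clustered each tissue separately and gave cluster numbers without names. Clusters were named here from fixed marker genes. Heart cluster 7 (1022 cells) and spleen clusters 3 (1731 cells, resting) and 4 (1390 cells, Klrg1 high) were regulatory T cell (Treg)-like. Other T-cell clusters, named or unnamed, formed the conventional class. Heart cluster 8 (954 cells), which led with fibroblast, B-cell and myeloid genes, and spleen clusters 5 (macrophage-like), 6 (unnamed), 9 (NKT-like or NK-like), 11 (unnamed) and 13 (B cell-like) were left out of both classes, as were 339 heart and 466 spleen cells without a cluster number. Treg cells numbered 257 to 407 per heart library, with median UMIs of 6446 to 7797, and 891 to 1282 per spleen library, with median UMIs of 4497 to 5947. No doublet caller was run. Cells with at least 2 productive beta chains made up 56.7% of heart cluster 8, 72.8% of spleen cluster 6 and 17.6% of heart cluster 7, and 1 alternative left out such cells together with cells above the 98th percentile of UMIs of their library.

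The comparisons, tests, marker genes, gene lists, rule for named genes and most alternatives were fixed before the data were examined; clonal expansion per cluster, clonotypes shared between tissues, cycling among conventional cells and some alternatives were added later. The fixed design assumed counts and prescribed limma on the mean log value per library and class for log-normalized tables. That fallback became the test of every gene comparison: limma 3.58.1 (empirical Bayes with a trend, R 4.3.3) on genes detected in at least 2% of cells in at least 3 of the sums compared, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Only the groups compared entered each fit. Treg and conventional cells of 1 tissue were compared with the library as a block. The interaction (Treg minus conventional in heart, minus the same in spleen) used all 12 sums with library terms. Differences are in natural log units (ln), as means over cells of the log value. Levels are in CPM (a gene's share of the recovered UMIs of the sum, on the usual CPM scale), as mean ± SD over 3 libraries, and folds are ratios of mean CPM. The mean of log values depends on how UMIs spread over cells and on cell depth, so edgeR 4.0.16 (quasi-likelihood, TMM or RLE size factors) and DESeq2 1.42.0 were run on the recovered UMI sums as alternatives.

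The tests were checked on simulated data, with Poisson counts for all groups drawn from the spleen Treg profile at real cell totals. The spread between libraries was preset and not estimated from the data, and fewer conventional cells were drawn. Changed genes were picked among genes detected in more cells than the filter asks. The rates below hold for these settings and may differ for the real classes, which mix several clusters. For heart against spleen Treg, 8 of 9415 unchanged genes passed the threshold. All of the genes raised 4-fold or 2-fold were recovered, as were 84% of those lowered 2-fold and 100% of those lowered 4-fold. For Treg against conventional cells of the heart, 50 of 9387 unchanged genes passed, 49 of them as higher in Treg. For the interaction, 14 of 9554 unchanged genes passed and 78% of genes lowered 2-fold were recovered.

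Of 27 gene lists, those with at least 3 tested genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The p-value of fry tests whether the genes of a list move on balance in 1 direction, its mixed p-value tests for changes in either direction, and neither compares the list with other genes. The preset correlation gave the calls reported. With an estimated correlation, 0 list calls held in the 5 gene comparisons. Lists of B cells, neutrophils, gamma-delta T cells, fibroblasts, cardiomyocytes, endothelial cells, erythroid cells and platelets had too few tested genes and are given as summed CPM. The genes named are the 10 highest and 10 lowest passing genes by difference (5 and 5 for the interaction) without overlap between groups and with at least 50 CPM in the higher group, leaving out TCR and immunoglobulin genes, predicted genes and markers of other cells. To these were added members of each list with the smallest p, and 19 genes of Treg and helper T-cell biology wherever measured, and some genes chosen by these rules are not reported here.

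A clonotype was the pair of CDR3 nucleotide sequences of the productive, high-confidence alpha and beta chains with the most UMIs in a barcode called a cell. Shares of cells in expanded clones (at least 2 cells) were compared after thinning to equal numbers of cells (mean of 100 draws). Clonotypes shared by Treg and conventional cells were set against 1000 random draws of class labels within a library. Shares of cells with a UMI were compared after thinning each cell to 2000 UMIs, which left out 0 heart and 14 spleen cells, 0 of them Treg. Shares and other values with 1 number per library were compared with exact two-sided permutation tests (smallest p 0.1 for 3 against 3 libraries) or exact two-sided sign-flip tests within libraries (smallest p 0.25). Confidence intervals are exact binomial (Clopper-Pearson, 95%) and cover counting error only. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

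Heart and spleen libraries of the same number shared 225, 258 and 166 clonotypes, against 1 to 7 for heart and spleen libraries of different numbers and 3 to 10 for libraries of the same tissue. Of the pairs of cells behind the shared clonotypes, 0 had the same barcode. The numbers were therefore taken to pair the samples, on the evidence of the receptors and not of the labels. The correlation of expression deviations between same-numbered libraries was 0.0550, 0.175 and 0.0937 in Treg sums and 0.0331, 0.262 and 0.0344 in conventional sums. The design without the pairing was kept for tissue comparisons, with the replicate number as a block as an alternative. Other alternatives were log2 values with pseudocounts of 0.01 and 0.1, no filter or a stricter filter, Treg defined by a Foxp3 UMI, omission of likely doublets or of cells with a Mki67 or Top2a UMI, thinning, each spleen Treg cluster alone, conventional cells without naive-like clusters, and omission of each library in turn.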

Results

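The largest clusters of the 3 heart libraries were named T helper 1 (Th1)-like and those of the 3 spleen libraries T follicular helper (Tfh)-like and naive-like cells. In heart, 3 Th1-like clusters held 20.7 ± 6.61%, 18.4% and 12.9% of all cells, followed by naive-like (8.91%), cycling (8.84%) and Th17-like (8.74%) clusters. In these 3 clusters, 0, 1 and 6 of 8 Th1 markers were over 2-fold higher than in the other heart cells, so few fixed markers support the name of the 2 largest. Their mean Th1 marker levels were 5.02, 6.30 and 8.79 counts per 10000, against 5.92 in the interferon cluster and 0.138 in naive-like cells. In spleen, a Tfh-like cluster held 19.4% of cells, naive-like clusters 17.7% and 17.7%, and a cluster led by markers of natural killer T (NKT) or NK cells 3.5%. Regulatory T cells, which restrain immune responses and depend on the transcription factor Foxp3, formed heart cluster 7 and spleen clusters 3 (resting) and 4 (Klrg1 high). A Foxp3 UMI was found in 58.4% of cells of heart cluster 7 (median 7387.5 UMIs), 65.5% of spleen cluster 3 (median 5274 UMIs) and 83.5% of spleen cluster 4 (median 5485.5 UMIs). B cells should lack Foxp3, and 5.36% of the B cell-like spleen cluster (median 5514 UMIs) had a Foxp3 UMI. With every cell thinned to 2000 UMIs, these shares were 34.7%, 39.7%, 59.1% and 2.5%.

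Treg made up a smaller part of the CD4+ T cells of the infarcted heart than of the spleen. They were 4.81 ± 0.489% of heart cells and 13 ± 0.992% of spleen cells, a difference of −8.15 percentage points with no overlap between the 3 heart and 3 spleen libraries (exact permutation p = 0.1). Clusters were made separately in each tissue, and Foxp3, which defines them, differed between heart and spleen Treg, so Foxp3 UMIs were also counted. Cells with one were 5.44% of heart and 14.6% of spleen cells, and 2.79% and 8.24% after thinning. Heart values were near the 5.36% and 2.5% of B cell-like cells and include 11.7% of heart cluster 8, so they do not isolate Treg. Among cells with a productive beta chain the shares were 5.05% and 13.2%.

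Cells with a UMI of the proliferation genes Mki67 or Top2a were 9.18 ± 2.26% of heart Treg and 5.48 ± 1.84% of spleen Treg after thinning, and 29.0% and 14.4% before (difference 3.70 percentage points after thinning, exact permutation p = 0.1; 2.45 without heart library 1). Such a UMI was also found in 3.12% of heart naive-like cells and in 1.79% and 1.08% of the spleen naive-like clusters after thinning, so these shares do not measure cycling cells alone, and the naive-like value was itself higher in heart. Against spleen cluster 4 alone, the Klrg1-high Treg, the values were 9.18% and 8.72% (exact permutation p = 0.9). Among conventional cells, 12.8 ± 1.96% of heart and 5.31 ± 1.85% of spleen cells had such a UMI after thinning (difference 7.53, exact permutation p = 0.1). The cycling clusters counted as conventional, and any Treg within them were left out of the Treg shares. After thinning, 2.02% of cells of the heart one and 12.7% of the spleen one had a Foxp3 UMI, against 2.5% of B cell-like cells. Among all cells with a Foxp3 UMI, the shares were 16.1 ± 4.98% in heart and 10.3 ± 3.79% in spleen, with overlap between libraries (difference 5.76, exact permutation p = 0.2). Between libraries of the same number, heart was higher in each case (21.7% against 13%, 14% against 11.9% and 12.5% against 5.96%).

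Heart Treg differed from spleen Treg in 4293 of 9629 genes, with 2445 higher and 1848 lower in heart. Odc1, which encodes the rate-limiting enzyme of polyamine synthesis, stood at 2280 ± 43.9 CPM in heart Treg and 161 ± 23.1 CPM in spleen Treg (14.1-fold, 2.30 ln). The transcription factor genes Bhlhe40 (1093 ± 32.7 against 88.5 ± 13.3 CPM, 12.4-fold), Rora (10.6-fold) and Id2 (6.66-fold) rose with it. So did Gna13, a G protein subunit gene (5.53-fold), the stress-response gene Gadd45b (4.97-fold), the intermediate filament gene Vim (3.46-fold), the galectin gene Lgals1 (2.35-fold), S100a6 (2.03-fold) and the protease inhibitor gene Ctla2a, which went from 26.5 ± 1.17 to 746 ± 124 CPM (28.1-fold). Klf2, whose product drives lymphoid recirculation, fell most on the ln scale, from 1061 ± 53.4 to 131 ± 8.97 CPM (8.12-fold lower, −1.43 ln). The condensin gene Smc4 fell 4.0-fold, the AP-1 gene Fos 3.88-fold, Tspan32 3.62-fold and Izumo1r 3.36-fold. The interferon-inducible GTPase gene Ifi47 fell 3.06-fold, Sp100 2.66-fold, Ms4a4b 2.33-fold and Gimap3 2.10-fold. In 5604 genes (58.2% of those tested, where chance gives 10%) the 3 heart libraries did not overlap with the 3 spleen libraries. On edgeR's ratio scale the split was 2501 higher and 2553 lower, so the excess of higher genes depended on the scale. With each cell thinned to 2000 UMIs, 2732 genes passed.

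Areg, encoding the growth factor amphiregulin, rose in heart Treg from 84.5 ± 7.16 to 490 ± 134 CPM (5.80-fold), and Il1rl1, encoding the interleukin-33 receptor ST2, from 6.35 ± 0.828 to 63.7 ± 11.9 CPM (10.03-fold). Ifng rose 8.58-fold, Tbx21 2.77-fold, Klrg1 1.99-fold, Ctla4 1.72-fold, Il10 1.65-fold (with overlap between libraries), and Pparg 3.77-fold at a low level of 3.67 CPM in heart. Small increases in Gata3 (1.32-fold, adjusted p 0.035) and Cd4 (1.15-fold, adjusted p 0.044) also passed, without overlap between libraries. Foxp3 was lower in heart (296 ± 9.99 against 382 ± 13.3 CPM, 1.29-fold), as were Ikzf2 (1.88-fold) and Nrp1 (1.79-fold). Il2ra (241 ± 27.0 against 195 ± 21.7 CPM, adjusted p 0.24) and Mki67 (17.8 ± 4.35 against 12.2 ± 4.82 CPM, adjusted p 0.11) did not pass; with the replicate number as a block, Mki67 passed with a difference of 0.03 ln (adjusted p 0.017). Ccr7 was lower by the mean of log values (−0.15 ln, adjusted p 0.0085) and higher in CPM (227 ± 6.47 against 189 ± 14.2) and in edgeR (0.30 log2). Several of these calls rested on single libraries. Il2ra passed without heart library 2 (adjusted p 0.042), and Mki67 without heart library 3 (0.014) or spleen library 2 (0.049). Nrp1 no longer passed without heart library 3 (0.077) or spleen library 1 (0.085), nor Ccr7 without spleen library 2 (0.065). Gata3 was lost without heart library 1 (0.18), spleen library 2 (0.062) or spleen library 3 (0.13), Pparg without spleen library 1 (0.072), 2 (0.092) or 3 (0.060), and Cd4 without heart library 1 (0.083), heart library 2 (0.12) or spleen library 3 (0.17).

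The list of tissue repair and effector Treg genes had 23 of 24 members higher in heart Treg and 0 lower, with Cxcr6 (19.6-fold), Ccr2 (3.35-fold) and Nfil3 (3.28-fold) among them (camera adjusted p = 8.1e-12; adjusted p = 0.067 with an estimated correlation). Extracellular matrix and matrix-binding genes had 11 of 12 higher, such as Cd44 (3.42-fold) and S100a4 (2.55-fold) (4.9e-10; adjusted p = 0.067 with an estimated correlation). All 15 tested Th1 genes were higher (2.9e-11; adjusted p = 0.085 with an estimated correlation). So were all 4 tested Th2 genes, Gata3, Ccr4, Ccr8 and Il1rl1, with Ccr8 at 4.94-fold (camera adjusted p = 0.0037, and 0.15 with an estimated correlation). The cytokine genes of the Th2 list, Il4, Il5 and Il13, were not tested, and Gata3, Ccr8 and Il1rl1 are also on the repair list. The Th2 call ended against spleen cluster 4 alone. Of the Th17 genes, 9 of 10 rose, including Il1r1 (11.8-fold) and Tmem176b (5.74-fold) (5.9e-06; adjusted p = 0.15 with an estimated correlation). Among 17 genes of glycolysis and hypoxia 16 rose and 1 fell, with Hilpda at 8.22-fold, Tpi1 at 3.16-fold, Hif1a at 2.38-fold and Gapdh at 2.06-fold (1.4e-08; adjusted p = 0.17 with an estimated correlation). Genes of lipid uptake and synthesis had 6 higher, 1 lower and 7 not passing. The triglyceride synthesis genes Dgat2 (19.9-fold) and Dgat1 (11.1-fold), the lipid droplet gene Plin2 (6.52-fold) and Fabp5 (4.43-fold) rose (0.035; adjusted p = 0.43 with an estimated correlation). Without spleen library 3 the list was no longer called.

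Signalling lists moved too. Of 14 NF-kB and TNF genes, 13 were higher and 1 lower, with Tnfsf11 at 8.93-fold, Nfkb2 at 2.94-fold and Nfkbia at 2.40-fold (2.6e-08; adjusted p = 0.15 with an estimated correlation). TCR signal genes had 11 higher, 2 lower and 4 not passing, with Nr4a3 at 6.15-fold, Tnfrsf9 at 3.07-fold and Tnfrsf4 at 2.32-fold (0.00068; adjusted p = 0.34 with an estimated correlation). Chemokine receptor and residency genes had 11 of 18 higher and 0 lower, such as Rgs2 (3.93-fold) (3.6e-05; adjusted p = 0.16 with an estimated correlation). Inhibitory receptors had 5 higher, 1 lower and 4 not passing, with Havcr2 at 6.04-fold and Tigit at 1.86-fold (0.049; adjusted p = 0.43 with an estimated correlation). This call ended without heart library 3, spleen library 2 or spleen library 3. Cell cycle genes had 12 higher, 1 lower and 7 not passing, with Cenpa at 2.21-fold and Hmgb2 at 1.87-fold (0.0021; adjusted p = 0.40 with an estimated correlation). Type I interferon response genes went down: 16 of 19 fell and 0 rose, with Usp18 7.18-fold, Ifit3 6.77-fold and Slfn1 3.05-fold lower (1.2e-11; adjusted p = 0.15 with an estimated correlation). Genes of naive cells and recirculation had 13 of 16 lower and 1 higher (camera adjusted p = 1.4e-08, and 0.17 with an estimated correlation). Igfbp4 was 19.4-fold and Klf3 3.39-fold lower. The naive call ended against spleen cluster 4 alone. Macrophage genes had 6 lower, 1 higher and 2 not passing, with Apoe 4.09-fold and C1qb 3.07-fold lower (0.0040; adjusted p = 0.30 with an estimated correlation). This call was lost without spleen library 3, and too few of these genes were left to test without spleen library 1 or 2.

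Lists without a call were mixed. Treg core genes had 9 higher, 6 lower and 2 not passing (adjusted p = 0.27), with Gpr83 14.6-fold lower. Tfh genes had 5 higher and 3 lower, with Icos 2.60-fold higher and Slamf6 2.94-fold lower (adjusted p = 0.71). Dissociation and heat shock genes had 11 higher, with Atf3 at 4.54-fold and Junb at 1.80-fold, and 5 lower, with Jun 2.66-fold lower (adjusted p = 0.11). CD8 T and NK cell genes had 2 of 4 higher, Klrk1 at 7.43-fold and Klrd1 at 3.38-fold (adjusted p = 0.19). Adjusted over the list alone, the counts were the same except for 1 more higher gene each in the repair (24), matrix (12), cell cycle (13), TCR signal (12) and lipid (7) lists. In total 15 of 19 lists were called, 12 of them higher and 3 lower in heart Treg.

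**Figure D1:**
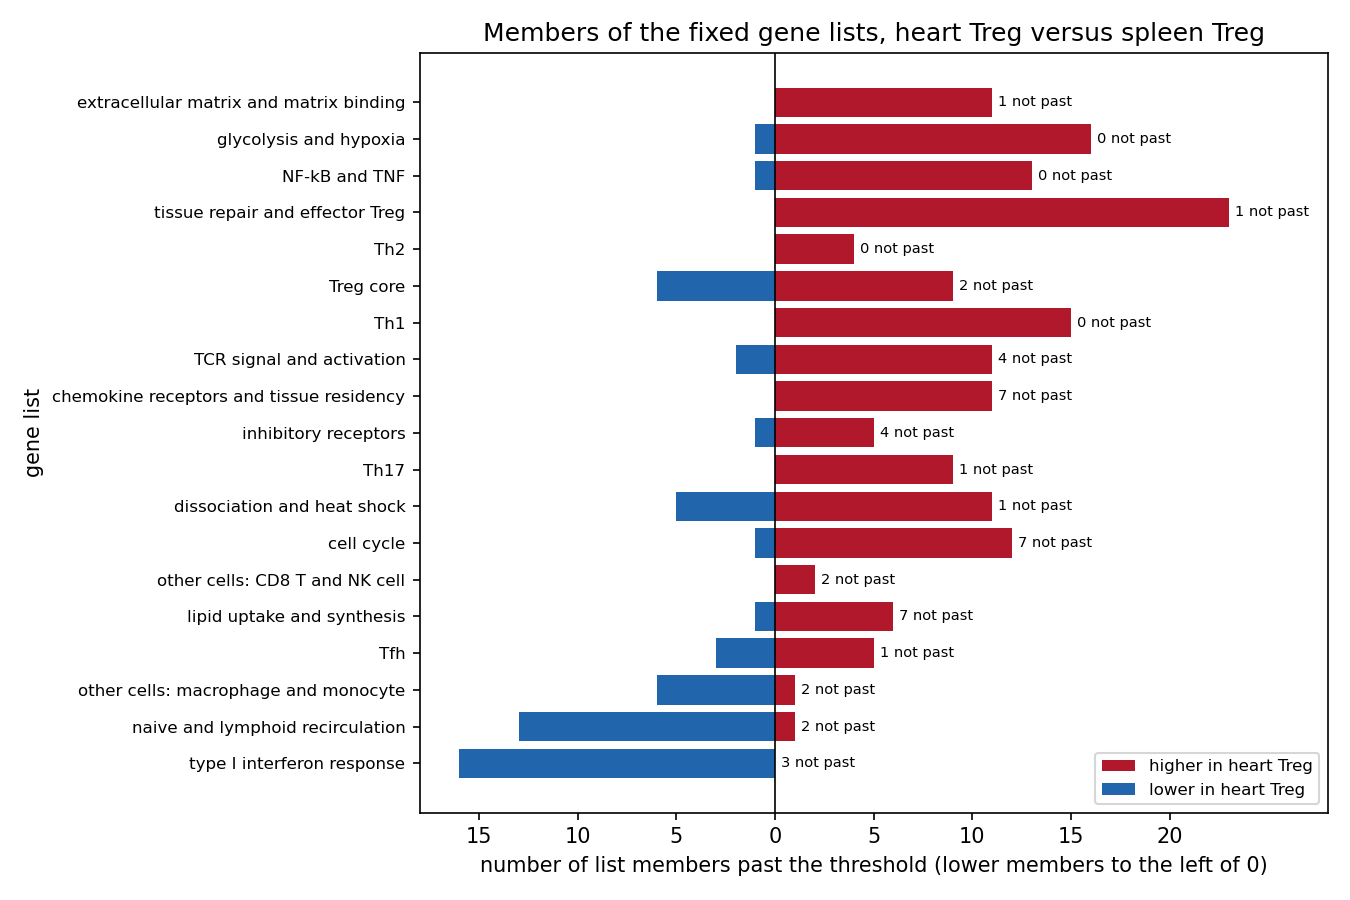
Number of genes of each list that passed the threshold between heart and spleen Treg (horizontal axis, higher in heart to the right of 0 and lower to the left), with the number that did not pass beside each bar. The repair list had 23 higher genes and 0 lower, and the type I interferon list 0 higher and 16 lower.

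Genes on the lists of other cell types were also summed in Treg. The source of this RNA was not tested, and a few genes can carry a sum. Of the macrophage genes in heart Treg, Ctss and Cst3 stood at 234 and 180 CPM, and Apoe and C1qb at 3.14 and 4.03 CPM. Summed over the genes of a list in both tables, heart and spleen Treg had 7.64 ± 1.35 and 44.8 ± 5.29 CPM of 6 B-cell genes, 446 ± 6.10 and 465 ± 10.5 CPM of 16 macrophage and monocyte genes, 36.9 ± 4.85 and 25.8 ± 1.32 CPM of 5 fibroblast genes, and 29.9 ± 5.39 and 50.5 ± 2.44 CPM of 6 endothelial genes (exact permutation p = 0.1 each). For 5 cardiomyocyte genes the sums were 45.4 ± 7.71 and 58.5 ± 11.5 CPM (exact permutation p = 0.3), for 9 CD8 T and NK genes 60.5 ± 36.8 and 40.8 ± 15.5 CPM (0.7), for 2 gamma-delta T-cell genes 1.67 ± 1.89 and 0.690 ± 0.295 CPM (0.6), and for 1 platelet gene 0 and 0.285 ± 0.153 CPM (0.1). Of the neutrophil and erythroid lists, 0 genes were in both tables. Sparc, a matrix-protein gene, had 34 UMIs in 26 of 1022 heart Treg (4.18 ± 2.08 CPM) and 0 UMIs in 3121 spleen Treg, at least 26.1-fold higher in heart against a floor of 3 UMIs over the group. Heart cluster 8, the mixed cluster with fibroblast genes, had 382 ± 92.6 CPM of Sparc. Sparc and Cd8a had too few positive cells for a test between tissues.

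Conventional CD4+ T cells of the heart differed from those of the spleen in 5668 of 9263 genes, 2745 higher and 2923 lower. Rgs1, a regulator of chemokine receptor signalling, rose from 157 ± 5.92 to 1960 ± 136 CPM (12.5-fold). Bhlhe40 rose 28.5-fold, from 39.5 ± 6.03 to 1123 ± 96.3 CPM, Odc1 17.0-fold, the interferon-gamma receptor gene Ifngr1 11-fold and the phosphatase gene Dusp5 9.56-fold. Vps37b (5.14-fold), Pim1 (3.92-fold), Nfkbia (3.56-fold), Srgn (3.41-fold) and S100a6 (2.49-fold) completed the 10 highest. The lowest were led by Klf2 (313 ± 34.9 against 1398 ± 94.1 CPM, 4.47-fold lower) and Fos (3.86-fold), and held Igfbp4 (4.59-fold), the naive T-cell transcription factor genes Lef1 (3.34-fold) and Tcf7 (3.28-fold), Dgka (3.06-fold), Jun (3.05-fold), Limd2 (2.40-fold) and Ccr7 (2.13-fold). The heart and spleen libraries did not overlap in 6461 genes (69.8%, where chance gives 10%). Without naive-like clusters 1998 genes were higher and 3565 lower.

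Among the genes always named, Areg rose 14.4-fold in heart conventional cells (82.7 ± 8.56 against 5.76 ± 2.41 CPM), Ifng 6.24-fold, Il2ra 3.09-fold, Ctla4 2.99-fold, Tbx21 2.65-fold, Mki67 1.89-fold (with overlap between libraries), Nrp1 1.62-fold, Klrg1 1.36-fold (with overlap) and Gata3 1.31-fold. Foxp3 was 1.93-fold lower, at 8.53 ± 1.69 against 16.5 ± 3.24 CPM. Treg in the cycling clusters, which counted as conventional, may add to this difference, which was not tested. Cd4 (183 against 210 CPM, adjusted p 0.18) did not pass. Ikzf2 did not either (28 against 45.7 CPM, adjusted p 0.17), and passed with the replicate number as a block (−0.03 ln, adjusted p 0.028). Without spleen library 3, Ikzf2 (adjusted p 0.0084) and Cd4 (adjusted p 0.0098) passed. Il1rl1, Pparg, Il10, Sparc and Cd8a were below the filter.

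Most lists that rose in heart Treg rose in heart conventional cells as well. All 14 tested Th1 genes were higher, with Cxcr6 at 9.02-fold, Fasl at 6.07-fold and Nkg7 at 4.62-fold (camera adjusted p = 1.3e-09; adjusted p = 0.25 with an estimated correlation). Repair genes had 17 of 18 higher, with Ccr8 at 16.3-fold and Rora at 11.9-fold (5.5e-10; adjusted p = 0.25 with an estimated correlation). NF-kB genes had 13 of 14 higher, with Tnfsf11 at 8.14-fold and Nfkb2 at 4.87-fold (1.5e-08; adjusted p = 0.25 with an estimated correlation). Matrix genes had 10 higher and 1 lower, with S100a4 at 3.64-fold and Lgals3 at 3.07-fold (4.9e-06; adjusted p = 0.25 with an estimated correlation). Th17 genes had 10 of 11 higher, such as Tmem176b at 3.42-fold (5.3e-05; adjusted p = 0.25 with an estimated correlation). Cell cycle genes had 18 higher and 2 lower, with Cenpa at 2.27-fold and Hmgb2 at 2.15-fold (3.1e-05; adjusted p = 0.39 with an estimated correlation). Chemokine receptor and residency genes had 10 of 17 higher, Rgs2 by 6.28-fold (0.00021; adjusted p = 0.36 with an estimated correlation). Glycolysis genes had 13 of 17 higher, with Hilpda at 7.20-fold and Hif1a at 3.44-fold (0.00023; adjusted p = 0.36 with an estimated correlation). TCR signal genes had 11 higher and 2 lower, with Nr4a2 at 10.1-fold and Nr4a1 at 4.10-fold (0.0011; adjusted p = 0.36 with an estimated correlation). Treg core genes had 12 higher and 3 lower, with Tnfrsf4 at 4.68-fold and Il2rb at 3.46-fold (0.0017; adjusted p = 0.41 with an estimated correlation). Dissociation genes had 12 higher and 3 lower, with Atf3 at 19.1-fold and Dnaja1 at 2.57-fold (0.014; adjusted p = 0.39 with an estimated correlation), a call that DESeq2 did not make.

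Naive and recirculation genes fell in heart conventional cells in 15 of 16 cases, with Dapl1 14.7-fold and Actn1 5.72-fold lower (3.3e-07; adjusted p = 0.25 with an estimated correlation). Type I interferon genes had 16 lower and 1 higher, with Usp18 5.39-fold and Ifi47 2.73-fold lower (4.9e-06; adjusted p = 0.36 with an estimated correlation). Macrophage genes had 7 lower and 1 higher, with C1qa 16.5-fold lower (0.0018; adjusted p = 0.38 with an estimated correlation), and too few were left to test without any 1 spleen library. No call was made for Th2 genes (2 of 3 higher, adjusted p = 0.11), lipid genes (5 higher and 3 lower, with Dgat1 10.8-fold higher, adjusted p = 0.34), inhibitory receptors (6 higher and 4 lower, with Tigit 3.56-fold higher and Btla 3.38-fold lower, adjusted p = 0.35) or CD8 T and NK genes (3 higher and 1 lower, with Klrk1 7.39-fold higher, adjusted p = 0.18). Tfh genes had 3 higher, with Icos at 5.63-fold, and 4 lower, with Cxcr5 9.58-fold and Slamf6 4.46-fold lower (adjusted p = 0.67); their median was −0.02 ln and camera pointed down, while their mean of 0.08 ln and fry pointed up. Adjusted over the list alone, glycolysis gained 1 higher gene (14) and the other counts did not change. Summed CPM in heart and spleen conventional cells were 2.59 ± 0.423 and 13.8 ± 1.65 for B-cell and 250 ± 8.08 and 325 ± 10.6 for macrophage genes (exact permutation p = 0.1 each). They were 22.8 and 32.3 for cardiomyocyte, 33.7 and 56.0 for endothelial, 102 and 73.3 for CD8 T and NK, and 2.63 and 1.27 for gamma-delta genes (exact permutation p = 0.1 each). For fibroblast genes they were 27.7 ± 4.19 and 24.8 ± 0.838 (0.4), and for platelet genes 0.199 and 0.226 (0.8).

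Within the heart, Treg differed from conventional cells in 4245 of 9335 genes, 3428 higher and 817 lower in Treg. The classes were named from Foxp3, Ikzf2, Il2ra, Ctla4, Tnfrsf18, Tnfrsf4, Izumo1r and Capg, whose higher levels in Treg (34.7-fold, 9.02-fold, 6.22-fold, 3.09-fold, 2.97-fold, 4.38-fold, 5.05-fold and 3.06-fold) follow from that naming. The clusters rest on these data, so other class differences, also in spleen, may partly follow from the clustering. Tnfrsf9 was 15.2-fold higher (643 ± 56.6 against 42.3 ± 7.38 CPM), Areg 5.92-fold, Itgav 5.53-fold and Mmd 4.09-fold. Ccl5 was 2.72-fold lower in Treg (694 ± 220 against 1889 ± 26.2 CPM), Ly6c2 3.70-fold, Gramd3 2.39-fold, Arid5a 2.01-fold, Dusp2 1.83-fold, Ctsw 1.76-fold, Ms4a4b 1.72-fold, Vps37b 1.62-fold, Hcst 1.52-fold and Nkg7 1.39-fold. Klrg1 was 27.5-fold higher (212 ± 73.4 against 7.71 ± 1.57 CPM) and Il1rl1 20.2-fold (63.7 ± 11.9 against 3.15 ± 0.793 CPM), Pparg 10.8-fold, Il10 6.86-fold, Gata3 2.07-fold, Nrp1 1.67-fold (with overlap between libraries), Ccr7 1.42-fold and Cd4 1.13-fold. Lower in Treg were Mki67 (4.23-fold), Tbx21 (1.54-fold) and, with overlap, Ifng (1.18-fold). With Treg defined by a Foxp3 UMI, Mki67 was higher (0.0816 ln, adjusted p 3.6e-05). That definition favours deep cells, cycling ones included, so depth may play a part here and below. Sparc did not pass (4.18 ± 2.08 against 4.06 ± 0.501 CPM, adjusted p 0.26), and the Ccr7 call ended without heart library 1 (adjusted p 0.071).

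The excess of higher genes in heart Treg depended on the scale: edgeR gave 2022 higher and 1967 lower. Heart Treg had more UMIs per cell, and in simulated data 49 of the 50 unchanged genes that passed were called higher. The groups did not overlap in 3763 genes (40.3%, where chance gives 10%), 2548 of the 4245 genes were also called in the same direction by edgeR, and 11 in the other.

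Lists of Treg biology were higher in heart Treg. All 16 core genes were, such as Itgae at 12.5-fold (camera adjusted p = 2.4e-18, and 0.13 with an estimated correlation). The genes used to name Treg are all on the core list, so its rise follows in part from the naming. Repair genes had 22 of 24 higher and 1 lower, such as Ccr8 (4.68-fold), Hopx (2.34-fold) and Nfil3 (2.01-fold) (1.3e-12; adjusted p = 0.13 with an estimated correlation). All 10 inhibitory receptor genes were higher, with Tox at 2.91-fold, Pdcd1 at 2.22-fold and Nt5e at 2.22-fold (1.5e-07; adjusted p = 0.13 with an estimated correlation). Glycolysis genes had 14 of 17 higher and 1 lower, with Tpi1 at 2.27-fold and Aldoa at 1.68-fold (7.0e-07; adjusted p = 0.24 with an estimated correlation). All 4 tested Th2 genes (no cytokine gene) were higher (camera adjusted p = 4.1e-05, and 0.15 with an estimated correlation). All 9 Tfh genes were higher, Tox2 by 4.18-fold (0.0026; adjusted p = 0.26 with an estimated correlation). Matrix genes had 8 higher and 2 lower, with Timp2 at 2.76-fold and Vim at 1.57-fold (0.0055; adjusted p = 0.18 with an estimated correlation). NF-kB genes had 10 higher and 2 lower, with Nfkb1 at 1.74-fold and Traf1 at 1.55-fold (0.0055; adjusted p = 0.18 with an estimated correlation). TCR signal genes had 11 higher and 2 lower, with Rel 1.95-fold higher and Cd40lg 2.05-fold lower (0.030; adjusted p = 0.24 with an estimated correlation). Lipid genes had 8 of 14 higher, with Dgat2 at 30.8-fold and Fabp5 at 3.10-fold (0.044; adjusted p = 0.26 with an estimated correlation). Without presumed doublets the TCR signal and lipid calls ended, and against conventional cells without naive-like clusters the matrix and TCR signal calls did. With Treg defined by a Foxp3 UMI the Tfh, TCR signal and NF-kB calls ended, and without heart library 3 the lipid call did (adjusted p 0.070). Summed CPM of genes on the lists of other cell types also differed between heart Treg and conventional cells. The sums were 446 against 250 for macrophage, 45.4 against 22.8 for cardiomyocyte, 36.9 against 27.7 for fibroblast and 7.64 against 2.59 for B-cell genes. Of the macrophage genes, Ctss and Cst3 stood at 234 and 180 CPM in Treg and 126 and 111 CPM in conventional cells.

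Proliferation genes were lower in heart Treg than in heart conventional cells: 18 of 23 fell and 2 rose, with Tuba1b 2.55-fold and Hmgb2 2.09-fold lower and H2afz 1.35-fold higher (1.8e-14; adjusted p = 0.15 with an estimated correlation). A cycling cluster counted among conventional cells; without cells with a Mki67 or Top2a UMI this list was not called, and with Treg defined by a Foxp3 UMI it was called higher. Naive and recirculation genes had 10 lower, with Igfbp4 19.5-fold and Klf2 2.39-fold lower, and 2 higher (2.3e-08; adjusted p = 0.13 with an estimated correlation). Th1 genes had 9 lower, with Fasl 2.42-fold lower, and 5 higher, with Id2 1.51-fold higher (3.7e-05; adjusted p = 0.18 with an estimated correlation). Dissociation genes had 10 lower, with Dnajb1 1.85-fold and Ier2 1.33-fold lower, and 5 higher (0.00020; adjusted p = 0.15 with an estimated correlation). CD8 T and NK genes had 3 lower and 1 higher, with Klrk1 3.03-fold lower (0.0027; adjusted p = 0.24 with an estimated correlation). Th17 genes (7 higher, with Ccr6 at 3.24-fold, and 2 lower, adjusted p = 0.27) and chemokine receptor genes (9 higher and 4 lower, adjusted p = 0.27) were not called. Interferon genes had 7 higher, with Ifi27l2a at 1.56-fold, and 5 lower, with Slfn1 1.64-fold lower (adjusted p = 0.46); their median of 0.02 ln and fry pointed up and camera down. Adjusted over the list alone, the naive list had 3 higher genes, the lipid list 9, and other counts did not change.

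Within the spleen, Treg differed from conventional cells in 4965 of 9341 genes, 3741 higher and 1224 lower; without spleen library 2 the count was 3180. With naive-like clusters left out of the conventional cells, 1814 genes were higher and 2113 lower, so the excess of higher genes depended on naive-like cells. The naming genes Foxp3 (23.1-fold), Il2ra (15.6-fold), Ikzf2 (10.4-fold), Tnfrsf4 (8.85-fold), Ctla4 (5.35-fold), Capg (5.15-fold), Tnfrsf18 (4.95-fold) and Izumo1r (4.33-fold) were again higher. Il2rb, encoding the interleukin-2 receptor beta chain, was 3.97-fold higher (420 ± 17.6 against 106 ± 20.1 CPM), Rgs1 3.32-fold and Dusp1 2.43-fold. Naive-cell genes led the lower side: Igfbp4 was 4.61-fold lower (121 ± 16.2 against 556 ± 81.3 CPM), Dapl1 5.93-fold, Cd40lg 3.46-fold, Fam101b 3.05-fold, Tcf7 2.64-fold, Lef1 2.16-fold, Satb1 1.86-fold, Ccr7 1.79-fold, Thy1 1.53-fold and Klf2 1.32-fold. Klrg1 (18.8-fold), Areg (14.7-fold), Il1rl1 (14.6-fold, at 6.35 CPM), Il10 (9.63-fold), Nrp1 (4.85-fold) and Gata3 (2.06-fold) were higher in Treg. Mki67 (3.26-fold, adjusted p 0.043), Ifng (1.62-fold, adjusted p 0.0065), Tbx21 (1.61-fold, adjusted p 0.023) and Cd4 (1.17-fold) were lower, the last 3 with overlap between libraries. Mki67 and Tbx21 changed direction with Treg defined by a Foxp3 UMI (0.11 ln, adjusted p 1.5e-06, and 0.0104 ln, adjusted p 0.13) and with cluster 4 as the only Treg (0.0222 ln, adjusted p 0.036, and 0.0110 ln, adjusted p 0.26). Without spleen library 1, the calls of Mki67 (adjusted p 0.22) and Tbx21 (0.15) ended, and without spleen library 2 those of Mki67 (0.19), Tbx21 (0.19) and Ifng (0.15). With edgeR 2718 genes were higher and 2756 lower, and the groups did not overlap in 4299 genes (46.0%, where chance gives 10%).

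In the spleen too, all 17 core genes were higher in Treg, Itgae by 22.6-fold and Tnfrsf9 by 8.77-fold (camera adjusted p = 6.2e-18; adjusted p = 0.13 with an estimated correlation). Repair genes had 21 higher and 1 lower, with Ccr8 at 15.4-fold and Maf at 2.29-fold (1.7e-11; adjusted p = 0.21 with an estimated correlation). NF-kB genes had 13 of 14 higher, with Icam1 at 2.44-fold, Traf1 at 2.08-fold and Nfkbia at 1.91-fold (4.7e-07; adjusted p = 0.33 with an estimated correlation). TCR signal genes had 15 higher and 1 lower (3.5e-05; adjusted p = 0.35 with an estimated correlation). Inhibitory receptors had 8 higher and 1 lower, with Entpd1 at 6.14-fold, Tigit at 3.25-fold and Lag3 at 2.75-fold (6.7e-05; adjusted p = 0.33 with an estimated correlation). Matrix genes had 9 of 11 higher, with Itgav at 5.08-fold and Vim at 1.35-fold (6.7e-05; adjusted p = 0.33 with an estimated correlation). All 4 tested Th2 genes (no cytokine gene) were higher (camera adjusted p = 0.0016, and 0.33 with an estimated correlation). Chemokine receptor genes had 14 higher and 2 lower, with Gpr183 1.56-fold lower (0.0029; adjusted p = 0.33 with an estimated correlation). Interferon genes had 15 higher and 3 lower, with Ifi27l2a 1.60-fold higher and Slfn1 1.40-fold lower (0.0085; adjusted p = 0.62 with an estimated correlation). Naive genes had 13 of 15 lower and 1 higher (8.5e-15; adjusted p = 0.13 with an estimated correlation). Against conventional cells without naive-like clusters, 8 of the 11 list calls in spleen held, and those of matrix, chemokine receptor and interferon genes ended. Spleen Treg had higher summed CPM than conventional cells for the macrophage (465 against 325), cardiomyocyte (58.5 against 32.3) and B-cell lists (44.8 against 13.8).

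Cell cycle genes had 11 lower, with Tuba1b 2.09-fold lower, and 3 higher, with H2afz 1.52-fold higher, in spleen Treg (4.0e-05; adjusted p = 0.49 with an estimated correlation). Without cells with a Mki67 or Top2a UMI this list was not called, and with Treg defined by a Foxp3 UMI it was called higher. No call was made for Th17 genes (3 higher, with Ccr6 at 1.80-fold, and 1 lower, adjusted p = 0.52), Tfh genes (5 higher, with Tbc1d4 at 1.94-fold, and 1 lower, 0.085) or glycolysis genes (9 higher, with Slc2a3 at 4.05-fold and Hif1a at 1.84-fold, and 4 lower, 0.56). Nor was one made for lipid genes (5 higher of 12, with Fabp5 at 1.76-fold, adjusted p = 0.67), macrophage genes (5 higher of 9, with Ctss at 1.57-fold, 0.085) or CD8 T and NK genes (1 higher and 2 lower, with Klrd1 5.85-fold lower, 0.054). Th1 genes had 4 higher, with Bhlhe40 at 2.24-fold, and 6 lower, with Gzmk 6.24-fold lower (adjusted p = 0.085). Dissociation genes had 5 higher, with Zfp36 at 1.43-fold, and 6 lower, with Ier2 1.33-fold lower (0.096). Tfh genes were called higher without spleen library 1 (0.0026) or 3 (0.0062). In the Th1 and dissociation lists, the median was −0.02 ln and camera pointed down, while the means of 0.02 and 0.05 ln and fry pointed up. Adjusted over the list alone, matrix genes had 10 higher, glycolysis genes 10 higher, cell cycle genes 12 lower, chemokine receptor genes 3 lower, and the other counts did not change.

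**Figure D2:**
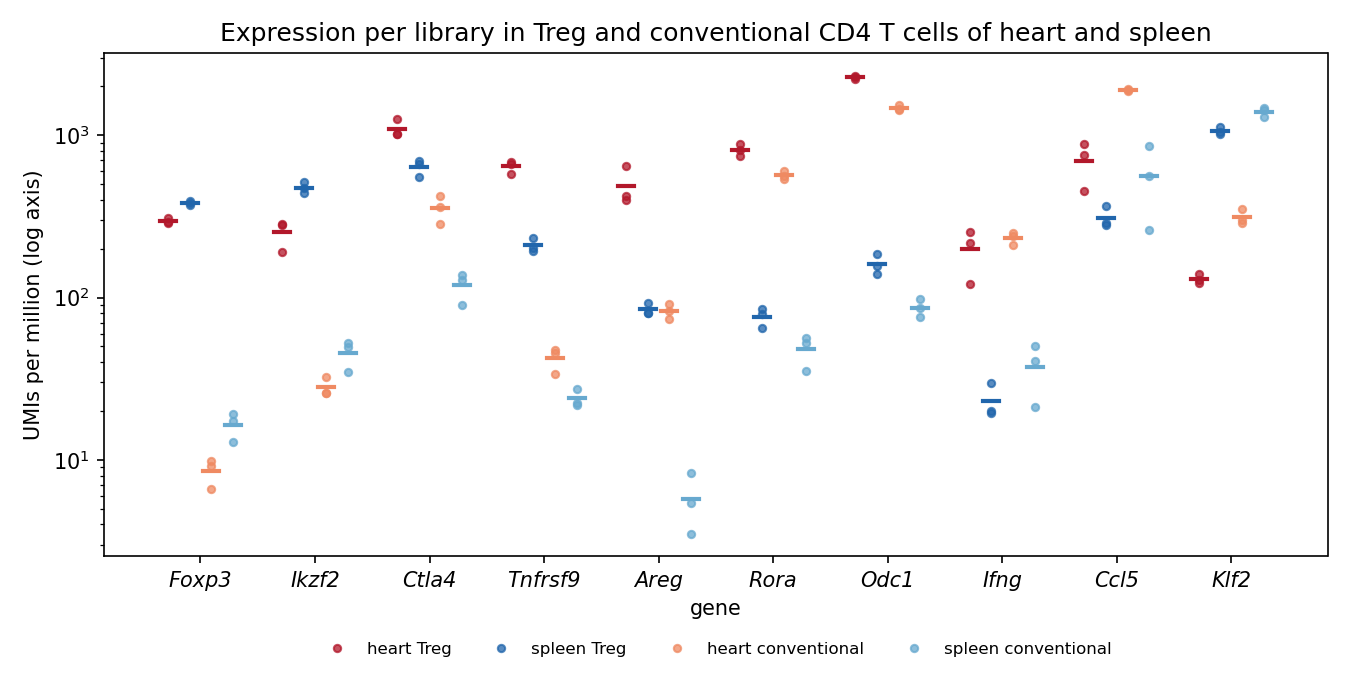
CPM (vertical log axis) of 10 genes in Treg and conventional cells of heart and spleen, with 1 point per library and a line at the mean of 3 libraries. Odc1 and Rora were higher in both heart classes, Areg was highest in heart Treg at 490 ± 134 CPM, and Klf2 was lower in both heart classes.

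The difference between Treg and conventional cells itself differed between tissues in 2243 of 9906 genes, 1421 higher and 822 lower in heart. On edgeR's ratio scale there were 2213 such genes, 1191 higher and 1022 lower, with TMM factors. RLE factors gave 981 higher and 1235 lower, and pseudocounts of 0.01 and 0.1 gave 888 and 981 higher and 1238 and 1336 lower, so the excess of higher genes depended on scale and normalization. With TMM factors, 1375 genes were called in the same direction on both scales while 58 changed direction. Genes with 1 direction on both scales are given here. Tnfrsf9 set heart Treg apart more (15.2-fold over conventional cells in heart, 8.77-fold in spleen; interaction 0.70 ln, edgeR 0.83 log2), as did Ccr7 (1.42-fold in heart and 0.557-fold in spleen; 0.60 ln, 1.40 log2) and Ly6a (1.61-fold and 1.10-fold; 0.59 ln, 0.59 log2). Rgs1 was higher in spleen Treg than in spleen conventional cells (3.32-fold) and lower in heart (0.739-fold; −1.04 ln, −2.12 log2), and so was Ifngr1 (2.54-fold and 0.795-fold; −0.87 ln, −1.64 log2). Il2rb (3.97-fold in spleen, 1.31-fold in heart; −0.63 ln, −1.56 log2) and Dusp1 (2.43-fold and 1.29-fold; −0.58 ln, −0.88 log2) set Treg apart more in spleen. Itgav (0.56 ln, 0.16 log2) and Ccl5 (−0.83 ln, −0.70 log2) kept their direction in edgeR without passing there (adjusted p 0.16 and 0.065). Igfbp4 (0.65 ln, −1.99 log2), Areg (0.54 ln, −1.31 log2), Ifng (−0.22 ln, 0.48 log2), Foxp3 (−0.21 ln, 0.61 log2), Il10 (0.09 ln, −0.39 log2) and Tbx21 (−0.07 ln, 0.16 log2) had opposite signs on the 2 scales, so no direction is given for them. Il2ra (−0.04 ln), Ctla4 (−0.05 ln), Gata3 (0.04 ln) and Sparc (0.01 ln) did not pass. Pparg (0.01 ln) was lost without spleen library 1 (adjusted p 0.079), 2 (0.12) or 3 (0.078), and Tbx21 without heart library 1 (0.053), spleen library 2 (0.059) or spleen library 3 (0.10). Il2ra passed without heart library 1 (0.047) and changed sign without heart library 2 (0.02 ln), as Gata3 did without heart library 1 (−0.01 ln).

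Among lists, glycolysis and hypoxia genes set heart Treg apart from conventional cells more than spleen Treg, with 10 higher and 2 lower of 17 (camera adjusted p = 8.1e-07; adjusted p = 0.15 with an estimated correlation), and this call held on both scales. Aldoa (1.68-fold over conventional cells in heart, 0.959-fold in spleen) and Tpi1 (2.27-fold and 1.21-fold) were among them. Lipid genes had 5 of 14 higher, with Dgat2 at 30.8-fold in heart and 5.98-fold in spleen, Fabp5 at 3.10-fold and 1.76-fold and Plin2 at 2.63-fold and 1.41-fold (0.0035; adjusted p = 0.15 with an estimated correlation). NF-kB genes had 7 lower and 2 higher, with Tnfaip3 at 0.813-fold in heart and 1.47-fold in spleen and Nfkbia at 1.29-fold and 1.91-fold (0.010; adjusted p = 0.25 with an estimated correlation). Dissociation genes had 10 lower and 2 higher (0.00022; adjusted p = 0.11 with an estimated correlation). Repair genes had 13 higher and 3 lower (0.0024; adjusted p = 0.11 with an estimated correlation) and were called lower in edgeR and DESeq2, so their direction depended on the scale. Interaction calls were also made higher for naive (11 higher and 2 lower; adjusted p = 0.082 with an estimated correlation), Th2 (3 of 4 higher; adjusted p = 0.11), Th17 (5 of 11 higher; adjusted p = 0.43) and inhibitory receptor genes (5 of 10 higher; adjusted p = 0.27). They were made lower for Treg core (7 lower and 4 higher; adjusted p = 0.15), cell cycle (13 lower and 3 higher; adjusted p = 0.25), Th1 (10 lower and 4 higher; adjusted p = 0.15) and interferon genes (9 lower and 3 higher; adjusted p = 0.42), each of these p-values with an estimated correlation. In edgeR with TMM factors, 7 of the 13 calls kept their direction: glycolysis, lipid and Th17 higher, and Treg core, NF-kB, interferon and dissociation lower. Naive, Th2, inhibitory receptor, cell cycle and Th1 genes were not called there. Th1 genes were called higher in 2 other edgeR settings, and interferon genes were called higher against conventional cells without naive-like clusters. The Th17 call ended without heart library 3 (adjusted p 0.34) or spleen library 2 (0.055), and the inhibitory receptor call without heart library 2 (0.076) or spleen library 3 (0.093). Matrix (6 higher and 3 lower, adjusted p = 0.20), Tfh (4 higher and 2 lower, 0.30), macrophage (1 higher, 0.78) and CD8 T and NK genes (2 lower, 0.055) were not called, though the last were called lower without heart library 2 (0.019), heart library 3 (0.047) or spleen library 1 (0.041). TCR signal genes had 5 higher and 5 lower (adjusted p = 0.65, median −0.00072 ln, mean 0.04 ln) and chemokine receptor genes 7 higher and 5 lower (0.71, median 0.05 ln, mean −0.02 ln). Adjusted over the list alone, the higher counts were 14 for repair, 7 for Th17, 5 for Tfh, 12 for naive, 12 for glycolysis and 10 for chemokine receptor genes. The lower counts were 15 for cell cycle, 11 for Th1, 1 for inhibitory receptors, 6 for TCR signal, 11 for interferon, 6 for chemokine receptor and 11 for dissociation genes, and the other counts did not change.

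CD4+ T cells of the heart were far more clonal than those of the spleen. Thinned to 4820 cells per library, 34.3 ± 2.5% of heart cells and 3.41 ± 1.05% of spleen cells carried a clonotype found in at least 2 cells, a difference of 30.9 percentage points in all 3 against 3 libraries (exact permutation p = 0.1; unthinned 36.9% and 4.48%). The TCR libraries held 4820 to 6632 cells with both chains in heart and 6248 to 8593 in spleen. The largest heart clone by number of cells, in library 2, had 71 of 6444 cells (1.10%, 95% interval 0.861% to 1.39%). It had a TRBV4 beta chain of CDR3 amino acids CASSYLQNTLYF, and lay mostly in a Th1-like cluster. The largest clone of heart library 3 had 67 of 6632 cells (1.01%, TRBV5) and that of heart library 1 57 of 4820 cells (1.18%, TRBV13-2), also mostly Th1-like. The largest spleen clone, in library 1, had 18 of 6455 cells (TRBV2) and had 23 cells in the heart library of the same number.

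Whether heart Treg were the more expanded class depended on how Treg were defined. At equal numbers of cells within a library, 10.5 ± 4.10% of heart Treg and 9.42 ± 0.0919% of heart conventional cells belonged to expanded clones (difference 1.13, exact sign-flip p = 0.75), and the difference was 3.29 without replicate 1 and −0.897 without replicate 2. With Treg defined by a Foxp3 UMI, the shares were 5.68 ± 2.22% and 10.5 ± 0.521%, lower in Treg in all 3 libraries (difference −4.80, exact sign-flip p = 0.25). In the spleen, Treg were the more expanded class in all 3 libraries (4.6 ± 0.417% against 1.17 ± 0.626%, exact sign-flip p = 0.25). Of 16164 conventional cells there, 8447 were naive-like, and some other clusters exceeded Treg (below). At 222 cells per library, 8.90 ± 2.82% of heart Treg and 1.62 ± 0.526% of spleen Treg belonged to expanded clones (difference 7.28, exact permutation p = 0.1). The largest Treg clones had 7, 6 and 4 of 345 Treg of heart library 2, and in spleen 5 of 745 in library 3 and 3 and 3 of 767 in library 1.

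**Figure D3:**
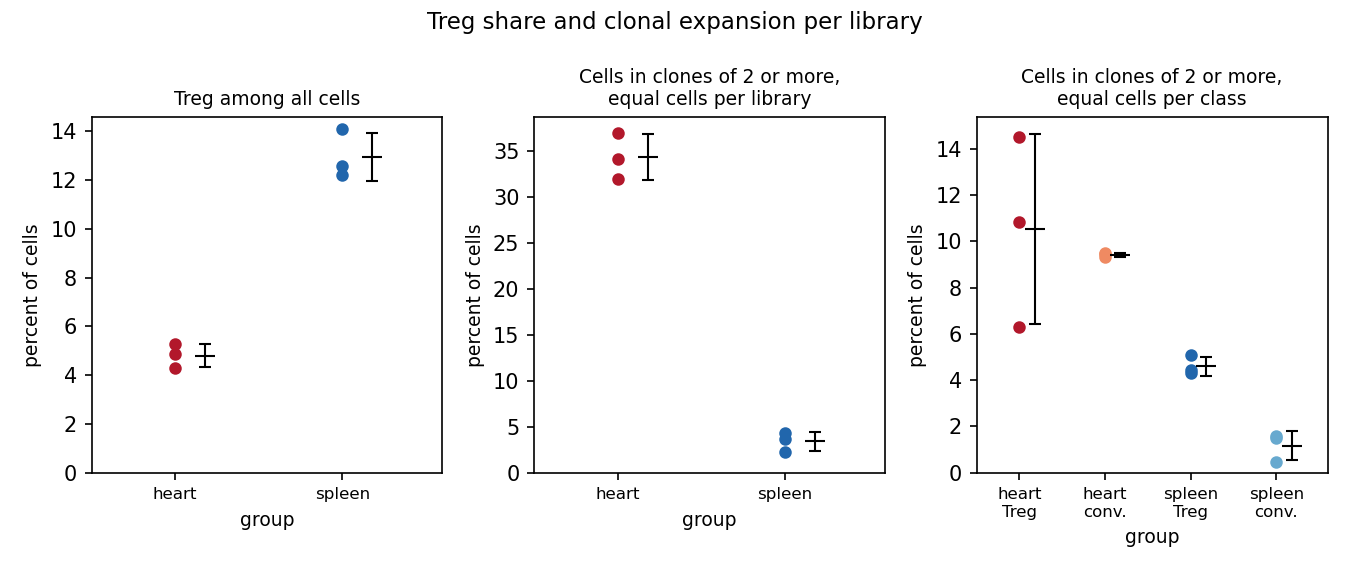
Percent of cells per library (points) with mean and SD over 3 libraries (black) for Treg among all cells, cells in expanded clones by tissue, and cells in expanded clones by class. Heart libraries had 4.81 ± 0.489% Treg and 34.3 ± 2.5% of cells in expanded clones, against 13 ± 0.992% and 3.41 ± 1.05% in spleen.

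Expansion differed between clusters. At 100 cells per cluster and library, 6.29 ± 1.23%, 7.14% and 17.4 ± 1.82% of cells of the 3 heart Th1-like clusters, 15.2 ± 1.91% of heart Th17-like cells, 7.45 ± 3.5% of cycling cells and 5.05 ± 2.25% of Treg-like cells belonged to clones of at least 2 cells, and 0% of naive-like heart cells. In the spleen, the values were 5.65 ± 2.68% in Th17-like and Th1-like cells, 4.93% in cycling cells, 2.68 ± 1.02% in Klrg1-high Treg and 0.0533% in resting Treg. Fewer clonotypes joined Treg and conventional cells than under random class labels. In heart, 24, 57 and 56 expanded clonotypes per library held a Treg cell, and 21, 47 and 50 of these also held a conventional cell, against 73.8, 111 and 112 expected to hold both, a ratio of 0.384 ± 0.0870. That most held both may be chance, as conventional cells outnumber Treg. In spleen, 22, 34 and 21 held a Treg cell, and 8, 12 and 8 held both classes against 29.6, 43.4 and 17.7 expected, a ratio of 0.333 ± 0.104.

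Clonotypes also joined the heart to the spleen. Of heart cells, 9.47 ± 0.832% of Treg and 10.8 ± 1.78% of conventional cells had a cell of the same clonotype in the spleen library of the same number (exact sign-flip p = 0.5). The spleen relatives of heart Treg were Treg in 18 of 95 cells (18.9%), against 11 of 663 (1.66%) for the relatives of heart conventional cells. Treg were 15.8 ± 2.06% of all spleen Treg and conventional cells with both chains. Cells of a clone are not independent, so no interval is given, and enrichment was not tested. By library, the relatives of heart Treg were Treg in 10.8%, 20.7% and 27.6% of cells, against 15%, 18.2% and 14.3% of all such spleen cells. For heart Treg clonotypes without a heart conventional cell, 15 of 36 spleen relatives were Treg (41.7%). Among spleen clusters, 29.0 ± 3.03% of Th17-like and Th1-like cells, 15.9 ± 3.85% of cycling cells, 8.81 ± 1.02% of Tfh-like cells, 2.31 ± 1.34% of Klrg1-high Treg, 0.122% of resting Treg and 0.0405% of naive-like cells had a heart relative.

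**Figure D4:**
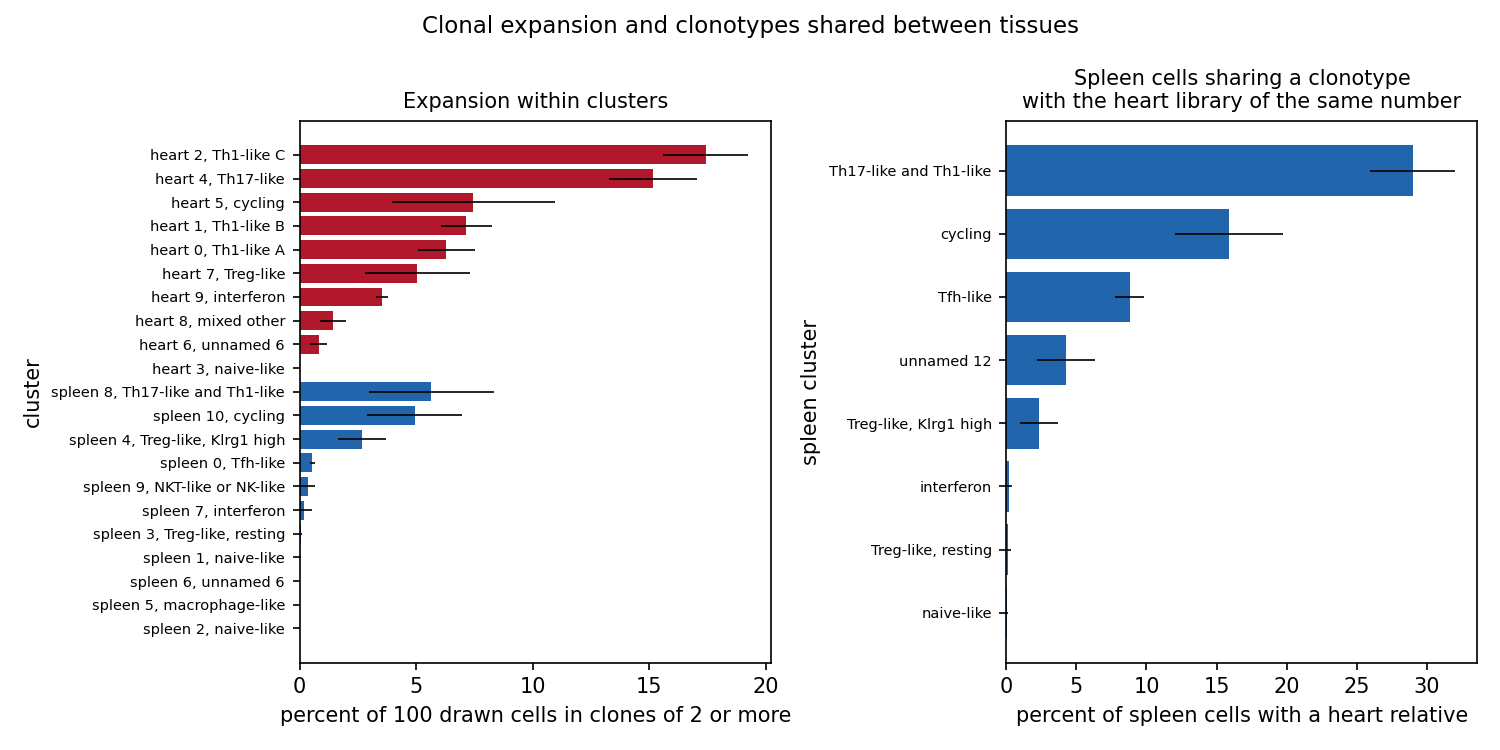
Percent of cells in clones of at least 2 cells at 100 cells per cluster (left, mean and SD of 3 libraries) and percent of spleen cells with a heart relative (right). A heart Th1-like cluster led at 17.4 ± 1.82%, and spleen Th17-like and Th1-like cells had the most heart relatives at 29.0 ± 3.03%.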

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

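The values from edgeR with TMM factors in this part came from a test chosen after the data were seen. The values here were singled out because the difference between Treg and conventional cells itself differed between heart and spleen in a test of the interaction, which 2243 genes passed. Among named genes with the same sign on the ln scale and in edgeR, these differences were positive, that is larger in heart, for Tnfrsf9 (0.70 ln), Ccr7 (0.60), Ly6a (0.59), Itgav (0.56), Aldoa (0.54), Dapl1 (0.39), Tpi1 (0.35), Dgat2 (0.29), Fabp5 (0.24), Klrg1 (0.24), Il1rl1 (0.22), Cd4 (0.21), Plin2 (0.20), Tox2 (0.18), Havcr2 (0.10) and Pparg (0.0130). They were negative for Rgs1 (−1.04), Ifngr1 (−0.87), Ccl5 (−0.83), Il2rb (−0.63), Dusp1 (−0.58), Ikzf2 (−0.52), Tnfaip3 (−0.47), Hmgb2 (−0.37), Nfkbia (−0.35), Lgals3 (−0.29), Btg2 (−0.26), Nrp1 (−0.24), Isg20 (−0.23), Fasl (−0.21), Gpr83 (−0.16) and Mki67 (−0.0598). For 6 genes the sign in edgeR was the opposite of the ln difference: Igfbp4 (0.65 ln), Areg (0.54), Ifng (−0.22), Foxp3 (−0.21), Il10 (0.0930) and Tbx21 (−0.0654). The Pparg and Tbx21 calls ended without single libraries, as given above.

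Medians of 13 lists were singled out for the same reason. The median interaction was 0.221 ln for glycolysis and hypoxia genes, 0.172 for naive and recirculation genes, 0.147 for Th2 genes, 0.0545 for inhibitory receptors, 0.0476 for repair genes, 0.0247 for Th17 genes and 0.0186 for lipid genes. It was −0.0934 for Th1 genes, −0.0898 for interferon genes, −0.0623 for dissociation genes, −0.0592 for NF-kB genes, −0.0507 for Treg core genes and −0.0360 for cell cycle genes.

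In the TCR tables, 504 barcodes carried a productive beta chain in the tables of both spleen library 2 and spleen library 3. The CDR3 nucleotides were the same for 193 of them (38.3%), against 0% to 0.418% in the other 14 pairs of libraries. The median was 1 UMI in library 2 and 12 UMIs in library 3, and 192 of the 193 barcodes were not called cells in library 2, so their contigs there entered no comparison. In library 3, 5 of the 193 were not called cells, and the contigs of the others were used.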

How the results depend on the processing

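Tests chosen after the data were seen were edgeR with TMM factors, cells thinned to 2000 UMIs, each spleen Treg cluster alone, conventional cells without naive-like clusters and, for Treg clone and cycling shares, Treg defined by a Foxp3 UMI. So were omission of presumed doublets and the share among Treg and conventional cells for the Treg share, the replicate block for cycling shares, and omission of cells with several beta chains for class clone shares and clonotype sharing. All alternatives were chosen later for cycling conventional cells and for clone shares of spleen classes and of heart against spleen Treg, as was leaving out replicates for clonotype sharing. For 307 named gene results, 6385 values were computed under alternatives. Of these, 6057 kept their direction and side of the threshold, 197 lost the call, 47 gained one and 84 changed sign. Of 298 called gene results, 245 were the same under every alternative run and 286 kept their direction. The interaction held 60 of the 84 sign changes and conventional cells between tissues 0. Unless a reason is given, the cause of a loss or change of sign was not tested.

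Cells thinned to 2000 UMIs gave 2732 genes between heart and spleen Treg (main 4293), 1776 between heart Treg and conventional cells (4245), 3052 in spleen (4965) and 958 for the interaction (2243). UMI sums thinned to the smallest total and tested with edgeR gave 2340 genes in heart and 889 for the interaction, and DESeq2 2631 and 1325. Spleen cluster 3 alone gave 3090 genes between Treg and conventional cells of the spleen. Without a replicate block, these within-tissue counts were 2681 in heart, 2065 in spleen and 666 for the interaction. With the replicate number as a block, 4782 genes and 15 lists passed between heart and spleen Treg, 6216 genes and 14 lists between conventional cells, and the exact p of Treg, cycling and clone shares was 0.25, the smallest possible. Besides Mki67 and Ikzf2 (in the report), the block changed no call of a named gene or list. With an estimated correlation, 0 lists were called in each of the 5 gene comparisons, and with a pseudocount of 0.1 the interaction had 8 list calls (main 13).

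Of the lists called, those called the same way under every other alternative that tested them were 10 of 15 between heart and spleen Treg, 13 of 14 between conventional cells, 8 of 15 in heart, 6 of 11 in spleen and 1 of 13 (glycolysis) for the interaction. Fewer than 3 macrophage genes were left to test between conventional cells without any 1 spleen library or at 2000 UMIs, between heart and spleen Treg without spleen library 1 or 2 or at 2000 UMIs, and fewer than 3 Th2 genes in spleen without library 2. Between heart and spleen Treg, the Th2 and naive calls ended against cluster 4. The inhibitory receptor call ended there, at 2000 UMIs, with Foxp3-UMI Treg, a pseudocount of 0.01, thinned sums or all 12 sums in 1 fit. The lipid call ended with Foxp3-UMI Treg, thinned sums or no Mki67 or Top2a cells, and the macrophage call in DESeq2. In heart, the CD8 T and NK call ended in edgeR and DESeq2, the TCR signal and lipid calls without a filter, and the lipid call also without Mki67 or Top2a cells. In spleen, the matrix call ended with both pseudocounts and with cluster 3 alone, the chemokine receptor call with cluster 3 alone, and the Th2 call without a filter. For the interaction, cell cycle, Th1, Th2, naive and inhibitory receptor calls ended or turned with both pseudocounts and in edgeR and DESeq2. The Treg core call ended with Foxp3-UMI Treg, at 2000 UMIs and with cluster 3 alone, and the NF-kB call in the last 2 of these. The dissociation call ended with cluster 4 alone, and the Th17 call there and without doublets or without Mki67 or Top2a cells. The lipid call ended in 2 edgeR settings, and the interferon call with Foxp3-UMI Treg. Repair genes turned lower in the interaction under a pseudocount of 0.01, edgeR and DESeq2, where ratios replace differences of log means. Th1 genes turned higher in 2 edgeR settings, and interferon genes without naive-like cells.

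Without 1 library at a time, counts of genes were 3336 to 3952 between heart and spleen Treg, 4720 to 5858 between conventional cells, 3152 to 3506 in heart, 3180 (without spleen library 2) to 4553 in spleen and 1506 to 2178 for the interaction. Counts of lists were 12 to 15, 13 to 14, 14 to 16, 10 to 12 and 12 to 14. The difference in Treg share was −8.54 to −7.59 points, in Treg with a Mki67 or Top2a UMI 2.45 (without heart library 1) to 4.65, in such conventional cells 6.42 to 8.25, and in clone share between tissues 29.6 to 32.1. Differences in clone share were −0.897 (without replicate 2) to 3.29 between heart Treg and conventional cells, 3.16 to 3.79 in spleen and 5.78 to 8.58 between heart and spleen Treg. Observed over expected sharing was 0.354 to 0.434 in heart and 0.273 to 0.365 in spleen. The interaction of Il2ra was −0.0933 to 0.0175 (without heart library 2), and that of Gata3 −0.0115 (without heart library 1) to 0.0790.

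Other definitions of the Treg share gave differences of −5.45 (Foxp3 UMI after thinning) to −11.0 (among Treg and conventional cells). The clone share between tissues differed by 20.8 (clones of at least 3 cells) to 35.8 (beta chain only). Between heart Treg and conventional cells it was −29.0 unthinned, where the classes differ in cell number, and −4.80 with Treg defined by a Foxp3 UMI. The alternative with only barcodes of the expression table gave no separate value for Treg against conventional cells, whose classes need that table. Observed over expected sharing was 0.510 in heart and 0.497 in spleen by beta chain, and 0.272 in heart with Foxp3-UMI Treg.

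Changes of sign in the interaction were as follows. With a pseudocount of 0.01, Igfbp4 was −2.07, Foxp3 0.51, Sparc −0.0260, Areg −1.20, Gata3 −0.0129, Il10 −0.36 and Ifng 0.31, and with 0.1, Igfbp4 −0.92, Foxp3 0.16, Areg −0.19 and Ifng 0.19. In edgeR with TMM or with at least 10 counts, Igfbp4 was −1.99, Foxp3 0.61, Areg −1.31, Il10 −0.39, Tbx21 0.16 and Ifng 0.48. RLE factors gave −2.03, 0.57, −1.34, −0.43, 0.12 and 0.44 and Gata3 −0.0131, and no filter −1.98, 0.62, −1.30, −0.38, 0.17 and 0.48. Thinned sums gave Igfbp4 −1.69, Foxp3 0.44, Areg −1.31, Il10 −0.45 and Ifng 0.35. DESeq2 gave Igfbp4 −2.25, Foxp3 0.58, Sparc −0.91, Areg −1.41, Gata3 −0.0139, Il10 −0.58, Tbx21 0.0632 and Ifng 0.35. Foxp3-UMI Treg gave Il2ra 0.0428 and Ctla4 0.21, spleen cluster 4 alone Il2ra 0.10, Klrg1 −0.0010, Gata3 −0.0828 and Il10 −0.0131, cluster 3 alone Ctla4 0.26, no naive-like cells Ctla4 0.10, and 2000 UMIs Ctla4 0.0123.

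Between heart and spleen Treg, Ccr7 turned higher: 0.27 and 0.25 with pseudocounts of 0.01 and 0.1, 0.30, 0.32, 0.27, 0.31 and 0.18 in edgeR (TMM, RLE, no filter, at least 10 counts, thinned), 0.31 in DESeq2 and 0.26 against cluster 4. Against cluster 4, Gata3 was −0.00012 and Mki67 −0.0055, and against cluster 3, Il2ra −0.0274. Between heart Treg and conventional cells, Sparc was −0.0547 with a pseudocount of 0.01, −0.13, −0.13, −0.17 and −0.13 in edgeR (TMM, RLE, no filter, at least 10 counts) and −0.14 in DESeq2. Foxp3-UMI Treg gave Mki67 0.0816 in heart and, in spleen, Mki67 0.11 and Tbx21 0.0104. In spleen, cluster 4 gave Mki67 0.0222 and Tbx21 0.0110, and cells without a Mki67 or Top2a UMI Tbx21 0.0012.

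Of the 10 splits of the 6 libraries or sums in each of the 5 gene comparisons, 1 gave as many genes, the real one, with 4293, 5668, 4245, 4965 and 2243 genes against 0 in the highest other split. Splits are too few for a share under 0.05. Depth limits rare transcripts: a gene that reached 2% of cells in fewer than 3 of the sums compared was not tested.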

Other observations

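Counts of V genes, invariant chains and naive-like cells by tissue were chosen after the data were seen, except the naive-like value for dissociation genes. TRBV31 was in 4.67 ± 0.461% of heart cells and 7.07 ± 0.194% of spleen cells, TRBV20 in 6.29 ± 1.23% and 4.37 ± 0.110%, and TRAV11 in 0.484 ± 0.159% and 2.14 ± 0.191% (exact permutation p = 0.1 each, the smallest possible, for the 3 largest differences of 113 V genes compared). With each clonotype counted once, the shares were 5.09% and 7.14%, 5.59% and 4.32%, and 0.643% and 2.18%. TRAV11 with TRAJ18, the invariant alpha chain of NKT cells, was found in 82 of 18997 heart cells (0.439 ± 0.174%) and 511 of 22101 spleen cells (2.27 ± 0.380%), of which 428 lay in the cluster with NKT or NK markers. TRAV1 with TRAJ33, the alpha chain of mucosal-associated invariant T cells, was found in 12 heart and 5 spleen cells.

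Naive-like cells, which are the least activated cells of both tissues by their markers, also differed between heart and spleen. Of 8451 genes tested, 1175 were higher and 3391 lower in heart. Interferon genes fell in 17 of 19 cases with a median of −0.218 ln, near the −0.274 ln of Treg. Among lists that rose in heart Treg, the median was −0.0113 ln for glycolysis genes (0.475 in Treg), 0.0394 for Th1 genes (0.550), 0.0906 for NF-kB genes (0.294) and −0.0989 for chemokine receptor and residency genes (0.106), over the genes tested in both. Depth ran opposite ways in the 2 classes. Median UMIs were 4335 in heart naive-like cells against 4706.5 and 5016 in the spleen clusters. In heart Treg they were 7387.5, against 5274 and 5485.5 in the spleen clusters. Values on this scale depend on depth, and no thinned or ratio-scale value of naive-like cells is given here. The difference between naive-like cells and Treg was not tested.

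Sparc was at least 26.1-fold higher in heart than in spleen Treg. In heart conventional cells, 472 UMIs gave 4.06 ± 0.501 CPM, and naive-like heart cells had 3.92 ± 1.61 CPM, both near the 4.18 ± 2.08 CPM of heart Treg. Cluster 8 held 5150 of the UMIs, in 44 of 954 cells. If free RNA of fibroblasts were the source, Sparc would keep a similar ratio to collagen RNA in Treg and conventional cells. Per UMI of Col1a1, Col1a2 and Col3a1, Sparc was 1.23 ± 0.551 in Treg and 1.0 ± 0.130 in conventional cells, and the smallest of the 3 per-library ratios of Treg to conventional cells was 0.648. In cluster 8, the class with fibroblast genes, Sparc was 0.553 ± 0.0958 per collagen UMI, and the Treg ratio was 2.27, 3.37 and 1.15 times that of cluster 8. The levels in Treg and conventional cells, and their ratios to collagen, go with free RNA. The ratio in cluster 8 cannot decide, since it rests on Sparc UMIs of 44 cells and need not be the ratio of free RNA. The source of Sparc stays open, expression by heart T cells included.

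Dissociation and heat shock genes had a higher median in heart than in spleen Treg, although camera made no call. As a hypothesis, tissue digestion may have raised them in heart cells of every type. The median difference in naive-like cells was 0.0775 ln over 16 genes against 0.109 ln in Treg, a ratio of 0.713. The list had 11 higher and 5 lower genes in Treg, and 9 higher and 5 lower in naive-like cells, so this ratio of medians decides nothing and the explanation stays open.

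The number of genes that differed between heart and spleen Treg may depend on depth, since heart Treg had more UMIs per cell. Thinned to 2000 UMIs, 2732 genes passed, below 1/1.5 of the 4293 in the full data. Of the 4293 genes, 2509 (58.4%) were called in the same direction after thinning. Thinning also removes UMIs from every cell and so loses calls for reasons other than the depth gap, which leaves the share due to depth open. The difference between tissues, which the design names, stays among the explanations for all 3 patterns, and no biological explanation was tested.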
